A study of Bos taurus with 20 samples.

How the data were processed

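The data were polyA RNA sequencing libraries from bovine satellite cells, the resident stem cells of skeletal muscle, taken from the Belgian Blue breed. Per the labels, cells grown with 20% fetal bovine serum were moved abruptly to a differentiation medium with 2% serum and harvested at 0, 24, 48, 72 and 96 h. Each of the 5 time points had 4 replicates, A to D, which gave 20 libraries. Per the labels, replicates A and B formed batch 1 and replicates C and D formed batch 2, so each batch held 10 libraries and every time point was split evenly between them.

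Per the labels' protocols, libraries were made with a stranded mRNA kit and sequenced to 75 bp. Per the submitters' processing notes, the tools were STAR 2.7 and featureCounts and the genome build was bosTau9. The order of these steps, their parameters, the strand setting and the annotation release are not given in the sources used here. The deposited values were raw read counts per gene, whole numbers that summed to a different total in each library. The table held 27607 genes, of which 6761 had a count of 0 in every library, and 0 lines that named no gene. All 20 columns were matched to a library by name.

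Genes were identified in the table by Ensembl cattle identifiers alone. The gene table given with the data, for assembly ARS-UCD2.0, paired 0 of these identifiers with a symbol, and its assembly differs from the build of the counts, so no symbols, positions or functions are given. The gene lists chosen before the data were examined, covering muscle regulators, sarcomere, cell cycle, metabolism, signalling and markers of other cell types, were therefore not tested, and neither was the planned scaling without listed genes. The rule for naming genes required a symbol and was applied without that requirement. It took called genes with a mean of at least 10 CPM over the 8 libraries compared and with no overlap between the groups, ranked by log2 fold change for 96 h against 0 h. The first 2 that rose and the first 2 that fell are named. The single gene of the batch by time test is also named and was chosen after its values were seen.

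Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr with a minimum count of 10 and a minimum total of 15, which left 14636 genes holding at least 99.967% of the counts of every library. Library sizes were scaled by TMM, and CPM values were computed on the scaled sizes. A quasi-likelihood model with terms for time point and batch was fitted to all 20 libraries with robust estimation. Each comparison was a two-sided quasi-likelihood F-test with Benjamini-Hochberg adjustment over the 14636 genes, and a gene was called at an adjusted p under 0.05. The same model tested all time points together, and a model with batch by time terms tested whether the time course differed between batches. Principal components used log2 CPM with a prior count of 2. The common biological coefficient of variation was 8.32%.

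Group profiles were described on mean log2 CPM. The time of the highest and lowest level was taken for genes called at any time with a range of at least 1 on the log2 scale. For the progress of the change, the counts held by changed genes and the 24 h highs followed between batches, genes were chosen in one batch and measured in the other. Genes with a range of at least 1, called excursions and the named genes were chosen and described on all 20 libraries, so their sizes are not free of selection. A passing excursion at 24 h required both the change from 0 h to 24 h and the opposite change from 24 h to 96 h, with the larger of both p-values adjusted over all genes. These descriptions of groups of genes and the scaling without the 10 most abundant genes were chosen after the data were examined. So were the tests of other groupings and of the 24 h highs between batches. The comparisons, their model, the filter and the other alternatives were chosen before the data were examined.

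Total counts ranged from 21100797 to 41998509 per library. At this depth, simulated changes between 24 h and 0 h were called for 40% of genes changed 1.25-fold, 86% at 1.5-fold, 96% at 2-fold and 100% at 4-fold, and 7.47% of the calls were genes that had not been changed. For the batch by time test the shares were 0%, 8%, 68% and 94%. These simulations ran on 14470 genes with 50 changed genes at each size, drawn from genes above a minimum mean count. For the batch by time test the change was set at 96 h in batch 2 alone. Few genes changed in the simulations, with 174 called for 24 h against 0 h, against 9683 in the data. The cut-off on the unadjusted p follows the number of calls, so these shares describe the simulated setting and not the real tests. Where a gene had 0 counts at a time point, folds were computed against a floor of 3 counts over the 4 libraries together. Where it had 1 to 3 counts, the ratio is given with an exact conditional binomial 95% interval. Intervals and floors cover counting error only, since reads without molecular identifiers are not independent molecules.

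Replicates were compared before averaging. Over genes with at least 20 counts, the chi-square per degree of freedom between replicates of a time point was at least 3.79, so no pair differed by as little as sampling noise and all 20 libraries were kept. The series describes the replicates as biological but does not say whether they came from separate animals, so p-values measure the spread between these cultures. Alternatives were DESeq2 1.42.0, RLE scaling, library sizes alone, scaling without the 10 most abundant genes, no filter, a stricter filter with a minimum count of 50, no batch term, the replicate letter as a block, each batch alone, the compared time points alone, a test against a 2-fold minimum with glmTreat, and the omission of each library in turn. Every split of the 8 libraries of a comparison into groups of 4 was also refitted, and 60 groupings of the 20 libraries for the test of any time. Figures were drawn with matplotlib 3.10.9 in Python 3.11.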

Results

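Gene expression was measured by polyA RNA sequencing in bovine satellite cells before (0 h) and 24, 48, 72 and 96 h after a change from medium with 20% serum to medium with 2% serum, with 4 replicates per time point. Satellite cells are muscle stem cells, and withdrawal of serum is a common way to make them differentiate in culture. Total counts per library averaged 30963732 ± 8171390 at 0 h, 25958737 ± 946562 at 24 h, 30204863 ± 8150719 at 48 h, 30133048 ± 5717599 at 72 h and 28917472 ± 6985859 at 96 h (SD, n = 4 each). Batch 1 averaged 32558093 ± 6093986 and batch 2 averaged 25913048 ± 4137273 counts (SD, n = 10 each).

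The 20 libraries separated by time point. The first principal component held 76.8% of the variance and ran from -136 ± 4.21 at 0 h through -43.3 ± 5.81 at 24 h and 42.4 ± 2.75 at 48 h to 65.3 ± 3.30 at 72 h and 71.3 ± 3.03 at 96 h (SD, n = 4 each). The second component, with 10.4% of the variance, went from -27.8 ± 5.34 at 0 h to 45.5 ± 3.03 at 24 h and back through 21.5 ± 4.65 at 48 h and -12.9 ± 7.78 at 72 h to -26.3 ± 4.31 at 96 h. On the third component, with 3.6%, 96 h lay at 24.7 ± 6.94 and 72 h at -19.5 ± 3.84, with 24 h at 13.3 ± 6.42, 0 h at -5.04 ± 2.06 and 48 h at -13.4 ± 5.16.

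**Figure D1:**
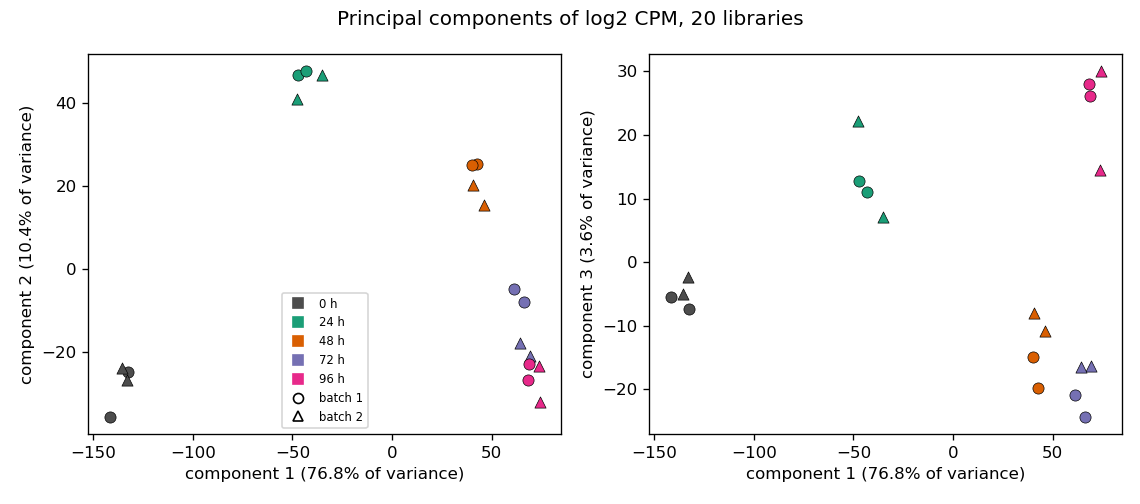
Principal components of log2 CPM for the 20 libraries, with component 1 on the horizontal axes and components 2 and 3 on the vertical axes, in arbitrary units. Colours are time points and symbols are batches; the 24 h libraries lie highest on component 2, between 40.98 and 47.57.

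The most abundant transcripts were replaced over the time course. The 10 most abundant genes at 0 h and the 10 most abundant at 96 h had 0 genes in common, while those at 0 h and 24 h shared 6 and those at 48 h and 96 h shared 8. The 10 genes that led at 96 h held 0.521 ± 0.00674% of all counts at 0 h, 1.79 ± 0.239% at 24 h, 7.25 ± 0.340% at 48 h, 9.51 ± 0.380% at 72 h and 11.5 ± 0.310% at 96 h (SD, n = 4 each). The 10 genes that led at 0 h fell over the same period from 5.39 ± 0.246% to 1.84 ± 0.116%. In each library's own 10 most abundant genes the share of counts went from 5.41 ± 0.270% at 0 h to 4.84 ± 0.173% at 24 h and 11.5 ± 0.311% at 96 h (two-sided exact permutation test, p = 0.0286 for 24 h against 0 h and p = 0.0286 for 96 h against 0 h, the smallest p that 4 against 4 libraries allow). The permutations moved libraries freely between batches and so ignored batch.

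The comparison of 96 h with 0 h asked how far expression had moved over the whole period of low serum. ENSBTAG00000040279 had 0 counts in all 4 libraries at 0 h and 28.9 ± 0.409 CPM at 96 h (SD, n = 4), at least 1350-fold higher, with a floor of 3 counts over the 4 libraries (edgeR quasi-likelihood test, adjusted p = 1.72e-18). ENSBTAG00000022714 rose from 2 counts in all to 65.3 ± 4.50 CPM (SD, n = 4), a ratio of 4540 with a 95% counting interval of 1260 to 37500 (edgeR adjusted p = 2.31e-17). ENSBTAG00000053073 went the other way, from 21.9 ± 2.65 to 0.110 ± 0.0746 CPM (SD, n = 4), a log2 fold change of -7.46 with a standard error of 0.21 (edgeR adjusted p = 6.56e-20). ENSBTAG00000033748 fell from 20.6 ± 1.20 to 0.124 ± 0.0348 CPM, a log2 fold change of -7.36 with a standard error of 0.25 (edgeR adjusted p = 2.71e-18). The separation of the 4 libraries at 96 h from the 4 at 0 h in these genes was required by the naming rule.

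Across all genes, 11770 of 14636 (80.4%) were called, with 5886 higher and 5884 lower at 96 h. Of the higher genes 2924 rose at least 2-fold, 1542 at least 4-fold and 630 at least 16-fold. Among the lower genes 2438 fell at least 2-fold, 839 at least 4-fold and 91 at least 16-fold. Of all genes in the table, 34 had 0 counts in every library at 0 h and at least 10 in each library at 96 h, and 3 genes showed the reverse. The 4 libraries of both time points did not overlap for 73.0% of genes, where chance gives 2.86%. A test against a 2-fold minimum called 4382 genes. With library sizes alone, which shifted the median of all genes to -0.40 on the log2 scale, the calls were 4007 higher and 8304 lower, so the split between directions is relative to the scaling. Higher and lower calls were close in number in every comparison, and the order of the counts turned in 4 of 20 alternatives here, 3 of 20 for 24 h against 0 h, 10 of 20 for 48 h against 24 h, 10 of 20 for 72 h against 48 h and 4 of 20 for 96 h against 72 h.

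**Figure D2:**
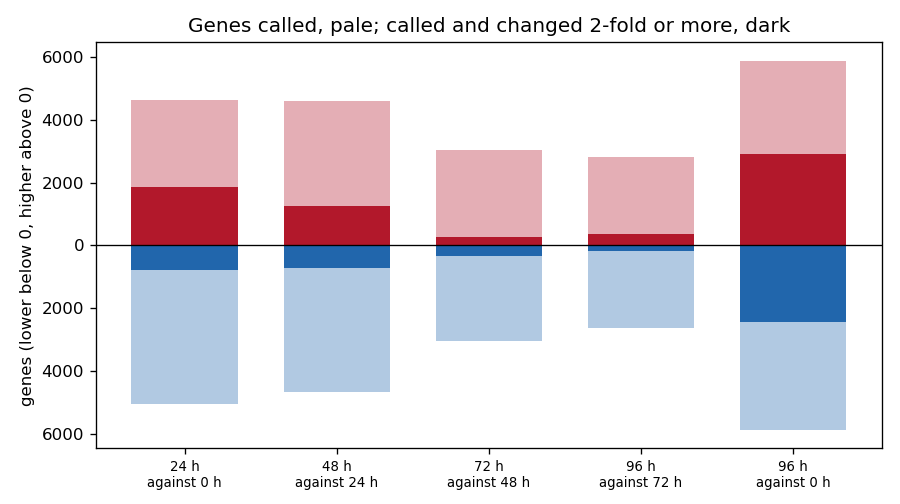
Number of genes called in each comparison on the vertical axis, with higher genes above 0 and lower genes below 0. Pale bars are all called genes and dark bars are those changed at least 2-fold; 2924 genes were at least 2-fold higher and 2438 at least 2-fold lower at 96 h than at 0 h.

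For genes at least 2-fold higher or lower at 96 h than at 0 h, the median log2 change had reached most of its 96 h size by 48 h. This describes the median of each group and not every gene. The 2899 genes at least 2-fold higher at 96 h in batch 1 had median log2 changes against 0 h of 0.95 at 24 h, 1.74 at 48 h, 1.85 at 72 h and 1.97 at 96 h in batch 2. The 2429 genes at least 2-fold lower in batch 1 had medians of -0.64, -1.33, -1.61 and -1.61 at the same times in batch 2. Genes chosen in batch 2 and measured in batch 1 had medians of 0.95, 1.79, 1.91 and 2.00 where higher and of -0.67, -1.33, -1.58 and -1.57 where lower. The median of the higher genes at 48 h was thus 88.4% of its 96 h value in batch 2 and 89.7% in batch 1.

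**Figure D3:**
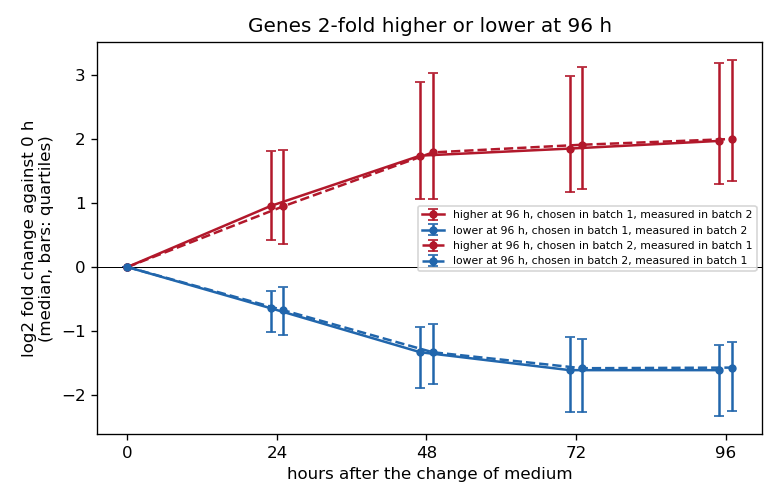
Median log2 fold change against 0 h, with quartiles as bars, by hours after the change of medium, for genes at least 2-fold higher or lower at 96 h in one batch and measured in the other. Solid lines are genes chosen in batch 1 and dashed lines genes chosen in batch 2; the higher genes reach 1.74 and 1.79 at 48 h.

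The comparison of 24 h with 0 h addressed the first day. ENSBTAG00000053073 had already dropped to 0.688 ± 0.0856 CPM at 24 h (SD, n = 4), a log2 fold change of -4.98 with a standard error of 0.15 (edgeR adjusted p = 2.70e-18), and ENSBTAG00000033748 to 1.62 ± 0.494 CPM, a change of -3.67 with a standard error of 0.16 (edgeR adjusted p = 2.13e-15). The rising genes were still near the limit of detection, with 10 counts over the 4 libraries for ENSBTAG00000040279 and 23 for ENSBTAG00000022714. For ENSBTAG00000022714, replicate C held 0.442 CPM and the others at most 0.126 CPM. Both genes were called higher (edgeR adjusted p = 0.00344 and 0.0077). ENSBTAG00000040279 was at least 3.77-fold above the floor of 3 counts, and ENSBTAG00000022714 had a ratio of 13 with a 95% counting interval of 3.22 to 114. In all, 9683 genes (66.2%) were called, 4636 higher and 5047 lower. The order of these counts turned with library sizes alone (5255 higher and 4254 lower), with the libraries of both time points alone (4599 and 4349) and in a test against a 2-fold minimum, which called 1738 genes (1263 and 475). Of the called genes, 1851 were at least 2-fold higher and 787 at least 2-fold lower, and 213 and 28 passed 16-fold. The groups did not overlap for 56.9% of genes, against 2.86% by chance.

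Between 24 h and 48 h the 10 genes that led at 96 h rose from 1.79 ± 0.239% to 7.25 ± 0.340% of all counts (SD, n = 4 each). ENSBTAG00000040279 reached 2.44 ± 0.208 CPM and ENSBTAG00000022714 6.63 ± 0.956 CPM at 48 h (SD, n = 4), with log2 changes from 24 h of 4.85 with a standard error of 0.32 and of 5.13 with a standard error of 0.30 (edgeR adjusted p = 3.79e-11 and 1.64e-11). Both rises started from few and uneven counts at 24 h, 0 to 6 per library for ENSBTAG00000040279 and 3 to 13 for ENSBTAG00000022714, so their size is uncertain. ENSBTAG00000053073 and ENSBTAG00000033748 continued to fall, with log2 changes of -1.29 and -2.12 (edgeR adjusted p = 0.000205 and 1.88e-07). The test called 9253 genes (63.2%), 4590 higher and 4663 lower, with 1266 at least 2-fold higher and 715 at least 2-fold lower. The groups did not overlap for 55.3% of genes, against 2.86% by chance. A test against a 2-fold minimum called 1091 genes, 859 higher and 232 lower. With library sizes alone the calls were 2667 higher and 8132 lower, at a median shift of -0.32 on the log2 scale.

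Between 48 h and 72 h fewer genes changed and by less. ENSBTAG00000040279 rose to 15.5 ± 2.48 CPM and ENSBTAG00000022714 to 38.6 ± 8.67 CPM (SD, n = 4), with log2 changes of 2.65 and 2.52 (edgeR adjusted p = 6.08e-11 and 4.59e-10). The 6065 called genes (41.4%) comprised 3028 higher and 3037 lower, of which 268 rose and 346 fell at least 2-fold. The median change of the called genes was 0.33 for those higher and -0.48 for those lower. The groups did not overlap for 31.3% of genes, against 2.86% by chance. With 2 libraries per group, batch 1 alone called 3740 genes and batch 2 alone 3749. A test against a 2-fold minimum called 115, with 88 higher and 27 lower. Library sizes alone gave 1878 higher and 4433 lower, at a median shift of -0.11.

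Between 72 h and 96 h the named rising genes continued to rise. ENSBTAG00000040279 and ENSBTAG00000022714 gained 0.90 and 0.77 on the log2 scale (edgeR adjusted p = 8.83e-06 and 0.000195). ENSBTAG00000053073 and ENSBTAG00000033748, at 15 and 18 counts over 4 libraries at 72 h, had changes of -0.18 and -0.43 that did not pass the test (edgeR adjusted p = 0.834 and 0.582). The test called 5459 genes (37.3%), 2824 higher and 2635 lower, of which 363 rose and 172 fell at least 2-fold. The groups did not overlap for 28.5% of genes, against 2.86% by chance. Batch 1 alone called 4750 genes and batch 2 alone 2495. A test against a 2-fold minimum called 86, with 63 higher and 23 lower. Library sizes alone gave 1984 higher and 3967 lower, at a median shift of -0.07.

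**Figure D4:**
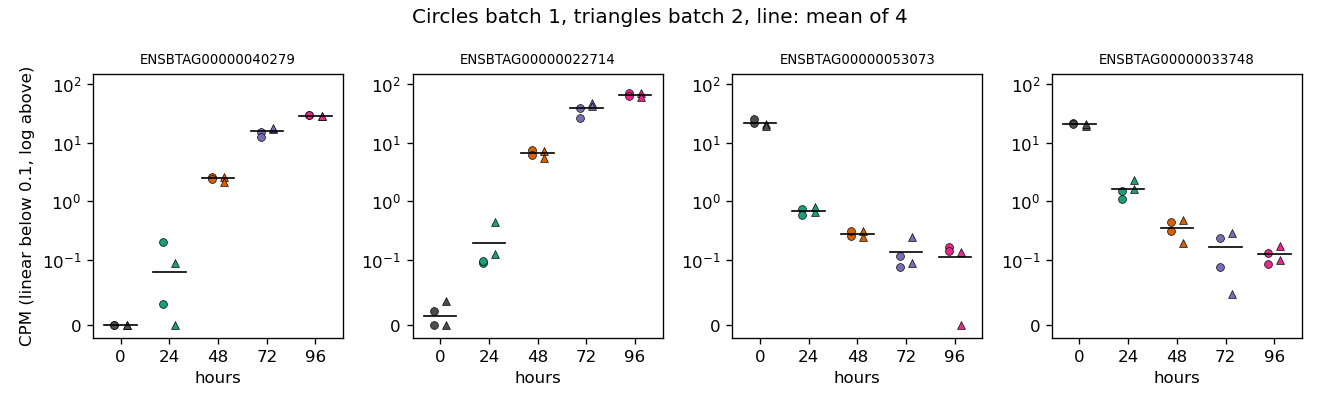
CPM per library of the 4 named genes against hours, on a vertical axis that is linear below 0.1 and logarithmic above. Circles are batch 1, triangles batch 2 and horizontal lines the mean of 4 libraries; ENSBTAG00000053073 drops from 21.9 to 0.688 CPM within 24 h.

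Taking all time points together, 13520 genes (92.4%) differed between at least some of them (edgeR quasi-likelihood F-test). Of these, 6906 had a range of at least 2-fold between time means. Their highest level lay at 0 h for 2651 genes (38.4%), at 24 h for 925 (13.4%), at 48 h for 721 (10.4%), at 72 h for 907 (13.1%) and at 96 h for 1702 (24.6%). The lowest level lay at 0 h for 3103 genes and at 24 h for 481. Of 7257 genes with such a range in batch 1, 81.1% were highest at the same time point in batch 2 and 94.1% at the same or a neighbouring one. The share at the same time point was 96.1% for genes highest at 0 h, 79.0% at 24 h, 65.5% at 48 h, 62.1% at 72 h and 76.5% at 96 h.

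Called excursions of any size at 24 h comprised 995 genes that rose and then fell and 965 that fell and then rose. This balance depended on the setting, with 975 and 1005 under RLE scaling, 2138 and 279 with library sizes alone, 738 and 764 in batch 1 alone and 497 and 336 in batch 2 alone. Among changes of at least 2-fold, passing rises were more frequent. In 258 genes the level at 24 h was at least 2-fold above 0 h and then fell at least 2-fold by 96 h, and in 42 genes it was lower by as much and then rose (edgeR, both steps called). These were 13.9% of the 1851 genes that rose at least 2-fold in the first day and 5.34% of the 787 that fell (two-sided Fisher's exact test across genes, which are not independent, p = 1.90e-11). The rising genes had also moved farther, with 858 at least 4-fold higher against 190 at least 4-fold lower. That leaves more room for a 2-fold return, and the test did not adjust for it. The 2-fold counts were 270 and 51 in batch 1 alone and 182 and 33 in batch 2 alone. With library sizes alone they were 446 and 26.

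The changes in batches 1 and 2 correlated across genes, less so in the later steps. Across 14636 genes, which are not independent replicates, the log2 changes in batch 1 and batch 2 had Pearson correlations of 0.982 for 96 h against 0 h, 0.949 for 24 h against 0 h, 0.935 for 48 h against 24 h, 0.799 for 72 h against 48 h and 0.646 for 96 h against 72 h, with Spearman values of 0.966, 0.902, 0.897, 0.779 and 0.569. Changes were also smaller in the later steps, which can lower a correlation by itself. The SD of the log2 changes over all genes was 1.1, 0.876, 0.476 and 0.449 from the first step to the last. Of genes changed at least 2-fold in batch 1, 99.0%, 99.4%, 96.6% and 92.6% kept their sign in batch 2 in these steps. The level differed between batches for 2816 genes, of which 14 differed at least 2-fold, and the median size of the difference over all genes was 0.10 on the log2 scale. The time course itself differed between batches for 1 gene, ENSBTAG00000021272 (edgeR batch by time F-test, adjusted p = 0.0212), which averaged 102 CPM in batch 1 and 77.0 CPM in batch 2 at 72 h and 38.6 and 51.6 CPM at 96 h (n = 2 each). At an unadjusted p under 0.05, 1423 genes (9.72%) passed, where chance alone gives a share of about 0.05. DESeq2 called 12 genes, and omission of the low-count filter gave 1154. In simulations with few changed genes this test recovered 8% of 1.5-fold differences.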

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

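Among 70 sets of 4 replicate values checked, 6 held a library far from the other 3 by Dixon's test, and chance gives about 1 in 20. The TMM scaling factor of replicate C was 0.948 at 48 h, where the others lay between 0.972 and 0.976, and 0.837 at 96 h, where the others lay between 0.858 and 0.861. The same libraries held the largest share of counts in the 100 most abundant genes, 24.6% at 48 h against at most 24.1% and 30.8% at 96 h against at most 30.3%. On the second principal component, replicate D at 24 h lay at 41.0, below the others at 46.6 to 47.6. ENSBTAG00000022714 was at 0.442 CPM in replicate C at 24 h and between 0.0946 and 0.126 CPM in the others.

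The time course of ENSBTAG00000021272 differed between the batches (edgeR batch by time test, adjusted p = 0.0212). Its level at 48 h was 48.2 CPM in batch 1 and 37.0 CPM in batch 2, and the order turned at 96 h, with 38.6 and 51.6 CPM.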

How the results depend on the processing

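The scaling without the 10 most abundant genes was chosen after the data were examined, and the other alternatives before. The gene list tests and the scaling without listed genes were not run, because no identifier had a symbol. Across the other alternatives, 124 values of gene counts stayed within 1.5 times the reported count and 15 did not. Many of these values came from refits without 1 library, and the measure ignores direction. Library sizes alone stayed within it for 96 h against 0 h, although 32.5% of the calls were higher, against 50% with TMM. A minimum of 2-fold in glmTreat, a stricter question, lowered the calls to 1738 for 24 h against 0 h, 1091 for 48 h against 24 h, 115 for 72 h against 48 h, 86 for 96 h against 72 h and 4382 for 96 h against 0 h. Single batches, with 2 libraries per group, called 3740 (batch 1) and 3749 (batch 2) genes for 72 h against 48 h, and batch 2 alone 2495 for 96 h against 72 h. The batch by time test called 12 genes with DESeq2 and 1154 without the low-count filter. It called 3 with 0 h left out, 3 with 24 h left out, and 0 with 48 h, 72 h or 96 h left out. The cause of the DESeq2 and time point differences was not tested. Without single libraries the calls ranged from 9195 to 9633 for 24 h against 0 h, 8722 to 9051 for 48 h against 24 h, 5185 to 5816 for 72 h against 48 h, 4393 to 5740 for 96 h against 72 h, 11509 to 11756 for 96 h against 0 h and 13448 to 13649 at any time. The 4 named genes kept their direction and call in 20 of 20 alternatives each. They had been chosen in these libraries for large changes without overlap, so this outcome was nearly fixed and says nothing about other genes.

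The replicate letters were not taken to pair the libraries, a choice that the correlations do not decide. Deviations of libraries with the same letter from their time means had a median correlation of 0.14 (range -0.35 to 0.53), with 22 of 40 pairs over 0.1, and 7 of 20 libraries correlated best with their own letter. From time and batch means the median was -0.08, with 4 of 40 pairs over 0.1 and 0 of 20 libraries best with their own letter. Taking off batch means by itself lowers correlations within a batch and raises them between batches, whether or not the letters pair libraries. Libraries with the same letter also share a batch, so neither set of values decides the pairing. With the letter as a replicate block the calls were 9590, 9111, 5896, 5290 and 11706 for the comparisons in time order with 96 h against 0 h last, and 13459 at any time, and no count moved by over 1.5 times. In simulations with few changed genes, the batch by time test, with 2 libraries per batch and time point, recovered 8% of 1.5-fold differences. The test of 24 h against 0 h recovered 86% there. Depth limits the named rising genes at 24 h, with 10 and 23 counts over 4 libraries.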

Other observations

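The tests of other groupings, of the size of the 24 h highs in the other batch, with and without the median change taken off, of the medium change and of genes of very low counts were chosen after the result was seen, and the last test of the unfiltered fit was chosen after the one before it had left the question open. By 96 h a large part of all counts came from genes that had been low. The 1432 genes that rose at least 4-fold by 96 h in batch 1 held 2.95% of the counts of batch 2 at 0 h, 10.2% at 24 h, 25.7% at 48 h, 30.3% at 72 h and 35.3% at 96 h (n = 2 each). The 783 genes that fell at least 4-fold in batch 1 went from 7.33% to 0.749% in batch 2. In the other direction of choice, 1426 genes went from 2.93% to 34.8% and 854 genes from 8.98% to 1.12% in batch 1.

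Genes with a passing high at 24 h were followed between batches. The 306 genes at least 2-fold above both 0 h and 96 h in batch 1 were above both ends by a median of 1.21 on the log2 scale in batch 2, and 97.1% were above both. The 254 genes chosen in batch 2 had a median of 1.37 in batch 1. Chance highs would have centred at or below 0 in the batch not used to choose them, so the tables argue against chance highs as the whole source. Of the 258 genes 99.2% stayed called under RLE scaling and 100% with library sizes alone, which alone decides little, since neither lowered 24 h by over 0.1 on the log2 scale against both ends. With the median change of all genes taken off each step, which removes any factor common to a library, genes chosen the same way still had median excesses of 1.22 and 1.36 in the other batch, so scaling does not account for highs relative to other genes. The change of medium itself may also act, and it cannot be told apart from the lower serum, since 0 libraries received fresh medium with unchanged serum. That these genes respond transiently to low serum is therefore a hypothesis that stays open.

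Without the low-count filter, 1154 genes differed in time course between batches, against 1 with it. Genes of very low counts were not their source, as 0 of the 1154 were genes that the filter removes. Without the filter the prior degrees of freedom became infinite, from a median of 9.2 with it, and reading the unfiltered statistics with the filtered degrees of freedom gave 367 genes, which alone leaves this explanation open. When scaling and dispersions were kept unfiltered and the prior spread was estimated over the filtered genes, 1 gene was called. The median prior degrees of freedom of that fit were 9.17, so it changed both together and does not separate them. A candidate explanation is therefore that low-count genes entering the estimate of the prior spread and its degrees of freedom made the unfiltered test too permissive. No biological explanation of the 1154 was tested.

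Other groupings of the same libraries were refitted for each comparison. Of the 35 splits of 8 libraries, 1, the real one, gave as many genes in each comparison. Every other split mixed libraries of both time points, so the time difference entered the spread within groups and lowered the calls. The refits therefore cannot decide how many genes would be called without a time effect. The real and the highest other counts were 9683 and 1 for 24 h against 0 h, 9253 and 0 for 48 h against 24 h, 6065 and 1 for 72 h against 48 h, 5459 and 695 for 96 h against 72 h and 11770 and 1103 for 96 h against 0 h. For any time, 1 of 60 groupings, the real one, gave as many, with 13520 genes against at most 7093. The 7093 came from a single shuffled grouping, and every other shuffled grouping called 0 genes. Why that grouping called so many was not tested. The split with 695 genes exchanged replicate C at 72 h with replicate D at 96 h, and on the third principal component that 96 h library lay at 14.6, against 26.1 to 30.0 for the others. The split with 1103 genes exchanged the same 96 h library with replicate A at 0 h. Those libraries lay far apart on the first component, at 73.7 and -141.7. Why these splits called genes was not tested.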
